A study of Mus musculus with 24 samples.

How the data were processed

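RNA was sequenced from mouse embryonic stem (ES) cells, wild type (WT) or lacking METTL3 (METTL3-KO), grown in naive conditions (2i and LIF) on the C57BL/6 background per the labels. Cells were left without inhibitor (mock) or given 200 µM of the translation elongation inhibitor emetine. RNA was taken 0, 1 and 3 h after actinomycin D blocked transcription. The 4 conditions (WT mock, METTL3-KO mock, WT emetine, METTL3-KO emetine) held 6 libraries each, 24 in all, with 2 replicates per condition and time point. Per the labels, total RNA was depleted of ribosomal RNA, ERCC spike-in RNA was added, and strand-specific libraries were made. The series' design text names the knocked-out gene as METTL14 while the sample labels name METTL3, and the table's header says only that a column is a knockout. The sample labels are followed here. A decay rate does not show whether a gene was knocked out, so the rates of Mettl3 and Mettl14 did not settle the point.

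The authors aligned the reads with STAR to GRCm38 and deposited 1 table with 15279 genes and 1 decay rate per condition. The deposited decay rates are positive where RNA was lost over the actinomycin D course. The read counter, the filter, the fitted model and the use of the spike-ins are not given in the sources used here. Unit and zero were inferred from the values. Rates that recur exactly in several genes, as rates computed from a few reads do, often lay 1, 4 or 5 fourteenths of the logarithm of a doubling apart, the steps of a least-squares slope over the 3 time points when 1 point doubles. With natural logarithms 272 pairs of recurring rates lay at such a step (absolute tolerance 1e-06 per hour), with log2 1 pair and with log10 0 pairs. The rates are therefore taken as natural log per hour, with the replicates merged before the logarithm. The 1st percentile of every column, over the genes with a rate in it, was 0 (tolerance 1e-09). Each condition thus carries an offset of its own, and a shift common to all genes between conditions says nothing about decay. The table holds no counts, expression levels or errors, so the depth behind each rate is unknown and no interval for a rate is given.

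The comparisons were fixed before the data were examined: METTL3-KO minus WT in mock and in emetine, emetine minus mock in WT and in METTL3-KO, and the interaction, which is the knockout difference in mock minus that in emetine. Each used the 13320 genes with a rate in all 4 conditions. The planned model across replicates needs a value per replicate, so in its place the planned description without a test was made, and no p-value is given. Differences were taken as deposited and after centring, which subtracts each condition's median over the 13320 genes. Changes of lists and gene groups are given relative to all genes, that is, centred, unless stated. The paired rates of named genes are as deposited, so their difference includes a common shift between the zeros. That common shift, which centring takes out, was -0.0215 (knockout, mock), -0.129 (knockout, emetine), 0.110 (emetine, WT), 0.00317 (emetine, METTL3-KO) and 0.107 (interaction). A further zero, the median of the ribosomal protein mRNAs, was also used. In WT emetine, 52 of these 55 genes lay above the median of all genes. In WT mock, METTL3-KO mock and METTL3-KO emetine the counts were 3, 3 and 5. This zero therefore carries that change into every comparison with WT emetine.

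The gene lists, 20 in number, were fixed before the data were examined: naive pluripotency, mRNAs described as m6A-marked in ES cells, immediate early and AU-rich, NMD-sensitive, ribosomal protein, replication-dependent histone, zinc finger protein, mitochondrially encoded, nuclear-encoded oxidative phosphorylation, TOP translation factors, chromatin regulators, m6A machinery, mRNA decay machinery, ribosome stalling and quality control, tRNA modification, and markers of primitive endoderm, trophectoderm, 2-cell-like cells, the primed state and fibroblasts. They were written from general knowledge, and the m6A-marked list does not come from a map of m6A. The lists of ribosomal protein, histone, zinc finger, mitochondrial and oxidative phosphorylation genes were taken by symbol. For each of the 18 lists with at least 3 measured genes, the median difference was placed among the medians of 10000 random lists of equal size, matched on the mean rate over the 4 conditions in 10 bins (random seed 1). Such bins match histone mRNAs loosely. Their median WT mock rate was 1.61 per hour, against 0.696 in the tenth of genes with the highest WT mock rates. A list is called outside the band when its percentile is below 2.5 or above 97.5. Chance puts 5% of lists there, or 4.5 of the 90 combinations of list and comparison. Genes are not replicates, so a percentile describes these libraries and carries no error from repeated experiments. In lists of 20 genes simulated from the 13320 genes for the knockout comparison in mock, 5% of 400 lists without a change, 65% of 100 lists shifted by -0.05 per hour and 100% of 100 lists shifted by -0.1 per hour lay outside the band. These lists were drawn at random, so the 5% follows from the design. The shares need not hold for lists of related genes or lists of mostly fast or slow mRNAs.

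Named genes follow a rule fixed before the data were examined. Per comparison it allows the 5 highest and the 5 lowest differences among genes with a symbol (predicted genes, pseudogenes, small RNAs and genes beyond the 1st or 99th percentile of any condition left out). It also allows the highest, lowest and median member of each list, any member of a list of 11 or fewer, and Mettl3 and Mettl14. The rule allowed 426 combinations of gene and comparison, of which the text names a part, chosen after the values were seen. Of the 40 genes allowed by size (50 combinations), 19 had a rate in some condition that recurred in another gene, against 597 of the 13320 genes, and genes with recurring rates are not used as examples. Symbols were looked up in a RefSeq gene table for GRCm38.p6, where 15158 matched directly and 56 by a synonym, while 65 did not match. Coordinates are from that table.

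Correlations across genes were computed between differences that share no condition. The alternatives fixed beforehand were the log2 ratio of rates, centring, the ribosomal protein zero, genes with positive rates only, genes within the 1st to 99th percentile, named gene symbols only, half-lives for the interaction, random lists matched on the WT mock rate, and list means. The WT mock rate is a term of the knockout difference in mock, the emetine difference in WT and the interaction, so errors in it enter both the matching and the difference there. Added after seeing the data were percentile ranks within conditions, the removal of genes with recurring rates, matching on the compared conditions only, and the ribosomal protein zero for the lists. No paired analysis was possible because the 2 replicates were merged into 1 rate. A screen of 232 groups of genes that share the letters of their symbol (at least 8 genes each, 2000 random lists per group) was also made after seeing the data. Transcript features such as exon length could not be computed, since no exon or coding-sequence annotation was used here. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.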

Results

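Messenger RNA decay was measured in mouse ES cells with and without METTL3, the catalytic subunit of the complex that writes m6A, a methyl mark on adenosines of mRNA. Both genotypes were studied with translation running (mock) and with translation blocked by 200 µM emetine, over 3 time points after transcription was stopped with actinomycin D. The 4 conditions comprised 6 libraries each. A decay rate was given for 14177 genes in WT mock, 14691 in METTL3-KO mock, 13702 in WT emetine and 14684 in METTL3-KO emetine, and 13320 genes had all 4. Each condition has a single rate per gene, without replicates or an error, and the depth behind the rates is unknown.

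The median rate over the 13320 genes was 0.319 per hour in WT mock, 0.297 in METTL3-KO mock, 0.429 in WT emetine and 0.300 in METTL3-KO emetine. These levels cannot be compared, because the zero of each condition is its own 1st percentile. Over all genes with a rate in each condition, the spread was widest in WT mock. Its interquartile range was 0.185 per hour, against 0.130, 0.111 and 0.101 in the other conditions in the same order. In mock, both genotypes ranked mRNAs alike across genes, which are not independent replicates (Spearman's rho 0.62). Between mock and emetine, rho was 0.43 in METTL3-KO and 0.18 in WT. WT emetine stood apart from the other conditions: its rho with METTL3-KO emetine was 0.12, and 5.77% of its rates recurred in another gene, a mark of few reads, against 2.12% to 2.55% in the others. Comparisons that use WT emetine carry that limit. Of the 90 combinations of list and comparison, 29 lay outside the band of random lists, against 4.5 by chance. In the comparisons without WT emetine these were 7 of 36, against 1.8 by chance. The combinations are not independent, since the 5 comparisons share 4 conditions and some lists share genes. The naive pluripotency and m6A-marked lists, for example, share 7 genes.

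**Figure D1:**
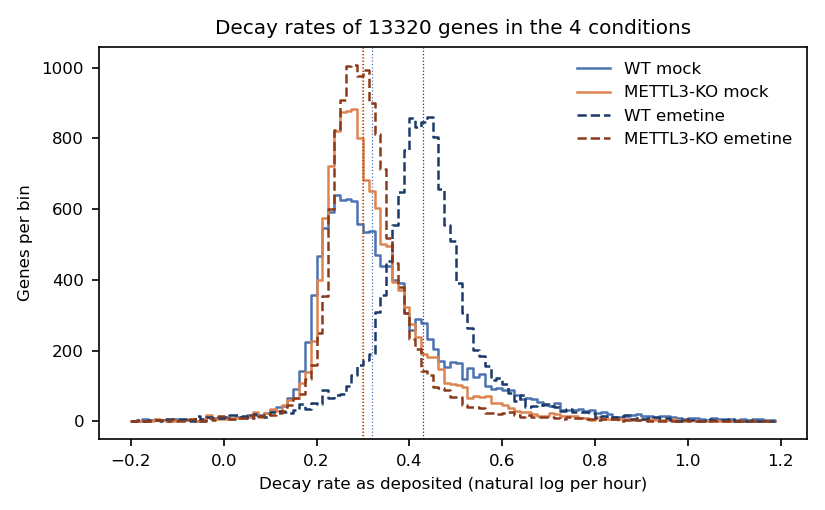
Number of genes (vertical axis, per bin) by deposited decay rate in natural log per hour (horizontal axis) for 13320 genes in 4 conditions, with dotted lines at the medians. The medians are 0.319 (WT mock), 0.297 (METTL3-KO mock), 0.429 (WT emetine) and 0.300 (METTL3-KO emetine) per hour, each on a zero of its own.

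The first comparison asked which mRNAs decay at another rate without METTL3 when translation runs. mRNAs of zinc finger proteins, a large family of mostly DNA-binding repressors, had lower rates in METTL3-KO than in WT relative to all genes: the median difference was -0.124 per hour (interquartile range -0.228 to -0.048), and 324 of 375 genes were lower. Immediate early and AU-rich mRNAs, which encode short-lived signalling regulators, were lower by a like amount, with a median of -0.151 (-0.251 to -0.057) and 29 of 33 genes lower. Both groups were among the fast-decaying mRNAs of WT cells, and their place in the ranking within conditions moved little. The median change of percentile rank was -2.39 for zinc finger mRNAs, below all random lists, and -0.090 for immediate early mRNAs, inside the band. Over all genes, rates were spread less in METTL3-KO mock (interquartile range 0.130 per hour) than in WT mock (0.185). The median rate was 0.605 per hour in WT and 0.442 in METTL3-KO for zinc finger mRNAs, and 0.789 and 0.602 for immediate early mRNAs. mRNAs of tRNA-modifying enzymes were higher relative to all genes by their median, 0.041 (-0.004 to 0.065), and 17 of 24 genes were higher. As deposited 14 were higher, and by its mean the list lay inside the band (percentile 77.0). The immediate early list also lay inside the band in some settings, given below.

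Zfp438, the median member of the zinc finger list, had 0.443 per hour in WT and 0.297 in METTL3-KO. The testis-expressed gene Zfp541, the highest, went the other way, from 0.131 to 0.488. Among immediate early mRNAs, Spry4, an inhibitor of receptor tyrosine kinase signalling, had 0.953 per hour in WT and 0.476 in METTL3-KO, and the stress-induced transcription factor Atf3 had 0.843 and 0.670. Of the tRNA-modifying enzymes, Ctu2 had 0.275 and 0.366, while its partner in tRNA thiolation, Ctu1, had 0.648 and 0.333.

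Among the mRNAs described as m6A-marked in ES cells, Klf2 had 0.790 per hour in WT and 0.376 in METTL3-KO, Klf4 0.890 and 0.512, Myc 0.920 and 0.506, Sox2 0.937 and 0.585, and Zfp42 0.634 and 0.452, all transcription factors of the pluripotency network or of growth. Nanog (0.392 and 0.333), Esrrb (0.360 and 0.325) and Med1 (0.409 and 0.352) differed less, and the Polycomb subunit Eed (0.413 and 0.463) and the RNA-binding protein Lin28a (0.138 and 0.234) were higher. Relative to all genes, 8 of the 11 were lower, with a median of -0.038 (-0.343 to 0.001) at the 43.1st percentile of random lists, inside the band. By its mean (-0.138) the list was nearer the edge, at percentile 4.96, also inside the band.

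Over all genes, the tenth with the highest WT mock rates had a median of 0.696 per hour in WT and 0.470 in METTL3-KO, and the tenth with the lowest 0.179 and 0.230. The WT rate is subtracted in the difference, so sorting by it partly fixes this trend, and genes picked for low differences, as the next ones were, have high WT rates by selection. The rate of Chac1, a glutathione-degrading enzyme induced by ATF4, was 1.15 per hour in WT and 0.404 in METTL3-KO. Pelo, which rescues stalled ribosomes, had 0.765 and 0.277. Rnf43, a ubiquitin ligase that removes Wnt receptors, had 0.954 and 0.176, the lowest difference of all genes the naming rule allowed by size. Its neighbours in that ranking included Dyrk3 (0.980 and 0.256). Ccdc150, with 0.171 and 0.774, was the highest. In coordinates of GRCm38, Klf2 lies on chromosome 8 at 72319062 to 72321654, Chac1 on chromosome 2 at 119351242 to 119354326 and Rnf43 on chromosome 11 at 87663087 to 87735539. Mettl3 itself had 0.398 and 0.436, and Mettl14 had 0.420 and 0.368.

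Of housekeeping mRNAs, the medians were 0.036 for ribosomal protein mRNAs (45 of 55 higher; Rpl21 0.248 in WT and 0.263 in METTL3-KO), 0.036 for oxidative phosphorylation (57 of 70 higher; Cox6c 0.227 and 0.240) and 0.050 for TOP translation factors, where all 16 were higher (Npm1 0.220 and 0.270). These 3 lists lay inside the band at percentiles 90.6, 86.0 and 97.2. Histone mRNAs had a median of -0.044, with 20 of 28 lower, at percentile 93.0, among random lists that match them loosely. H1f4 had 1.55 per hour in WT and 1.49 in METTL3-KO, H2bc4 1.56 and 1.16, and H4c9 1.12 and 1.34. The m6A machinery list stood at -0.044 (12 of 18 lower), just inside the band at percentile 2.61. The writer subunits Cbll1 (0.684 and 0.429) and Zc3h13 (0.385 and 0.313) were lower, and the reader Ythdc2 (0.387 and 0.429) was higher.

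Other lists lay inside the band as well by their medians. Their medians were -0.0090 for naive pluripotency (12 of 22 lower), -0.015 for chromatin regulators (19 of 33 lower), -0.059 for primitive endoderm (4 of 8 lower), -0.083 for trophectoderm (4 of 7 lower), -0.034 for primed state (3 of 6 lower) and -0.059 for fibroblast markers (3 of 3 lower). By its mean (-0.150) the primitive endoderm list lay outside the band (percentile 0.93). NMD-sensitive mRNAs (0.016, 9 of 16 higher), mRNA decay machinery (0.0084, 13 of 25 higher) and ribosome quality control (0.021, 11 of 16 higher) had medians above 0 after centring, but below 0 as deposited and against the ribosomal protein zero, and means below 0 throughout. Examples were Srsf2 (0.325 in WT and 0.394 in METTL3-KO), Utf1 (0.330 and 0.428), Tob1, an adaptor of the deadenylase complex (0.960 and 0.699), and Sox17, an endoderm regulator (1.14 and 0.318). No mitochondrially encoded gene was in the table, and of the 2-cell-like markers only Tcstv3 had a rate in all 4 conditions.

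Matching the random lists on the WT mock rate, as planned, placed the zinc finger list at percentile 72.5 and the immediate early list at 74.7, but decides nothing, because that rate is itself subtracted in the difference and its errors enter both. Matched on the mean of both mock conditions, the zinc finger list stayed below all random lists and the immediate early list moved inside the band (7.995). The immediate early list also lay inside the band by its mean (3.88) and by ranks (41.6), and the tRNA modification list by its mean (percentile 77.0), which as deposited was -0.00432. Over all genes the direction depended on the zero, with 58.0% of genes lower as deposited, 46.0% after centring and 62.7% against ribosomal protein mRNAs.

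**Figure D2:**
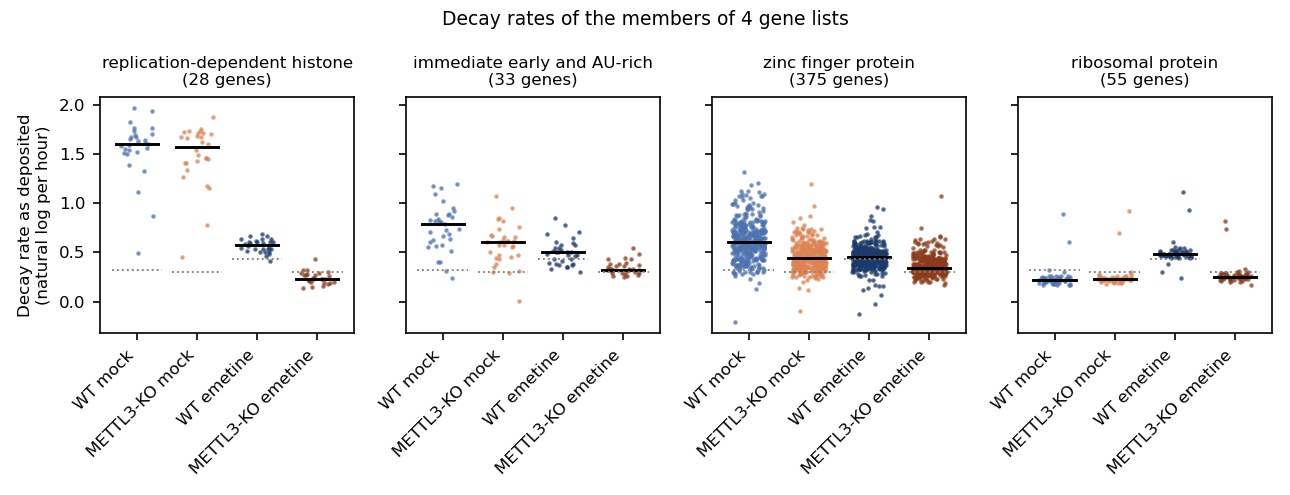
Deposited decay rates (natural log per hour, vertical axis) of the measured members of 4 gene lists in the 4 conditions; each point is a gene, black bars are list medians and dotted lines the medians of all 13320 genes. Histone mRNAs have medians of 1.61 and 1.57 per hour in mock against 0.580 and 0.234 in emetine (WT and METTL3-KO), and zinc finger mRNAs 0.605 in WT mock against 0.442 in METTL3-KO mock.

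The second comparison repeated the knockout contrast with translation blocked. Histone mRNAs, which end in a stem-loop instead of a poly(A) tail, had lower rates in METTL3-KO emetine than in WT emetine, with a median of -0.217 per hour (-0.253 to -0.138) and 27 of 28 genes lower (median -0.346 as deposited and -0.115 against the ribosomal protein zero). Ribosomal protein mRNAs were lower relative to all genes, with a median of -0.098 (-0.137 to -0.059) and 54 of 55 lower, but near 0 (0.0043), by construction, when they serve as zero themselves. Oxidative phosphorylation (-0.073, 61 of 70 lower) and TOP translation factors (-0.072, 15 of 16 lower) were lower relative to all genes and higher against the ribosomal protein zero (0.029 and 0.030). Zinc finger mRNAs were higher relative to all genes, with a median of 0.048 (-0.045 to 0.117) and 240 of 375 higher, and higher against the ribosomal protein zero (0.149), but lower as deposited (-0.081).

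The median histone mRNA, H2bc6, had 0.589 per hour in WT emetine and 0.243 in METTL3-KO emetine, and H2bc9 had 0.636 and 0.156, while H1f4 had 0.412 and 0.300. Rps3, of the small ribosomal subunit, had 0.474 and 0.248 and Rpl36a 0.537 and 0.202, while Rpl39l, a paralog expressed mainly in testis, had 0.239 and 0.252. Of the respiratory chain and ATP synthase, Atp5k had 0.593 and 0.228 and Ndufb11 0.429 and 0.228. The elongation factor Eef1a1 had 0.502 and 0.235, and the initiation factor subunit Eif3e 0.422 and 0.348. Among zinc finger mRNAs, Zfp518b stood at the median with 0.378 and 0.297, Zfp82 at the top with 0.563 and 1.08, and Zfp629 at the bottom with 0.963 and 0.456. These pairs are as deposited. Relative to all genes, H1f4 (0.0171), Eif3e and Zfp518b were higher, since their fall was smaller than the common shift of -0.129.

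The pluripotency factor Utf1 had 0.642 in WT emetine and 0.262 in METTL3-KO emetine, and the germ-cell regulator Dppa3 0.167 and 0.333. Of the m6A-marked mRNAs, Myc had 0.548 and 0.322 and Lin28a 0.275 and 0.230, and the list's median was -0.024 (7 of 11 lower) at percentile 22.7, inside the band. Mettl3 had 0.449 and 0.272, and Mettl14 0.393 and 0.347. Centring takes the common shift of -0.129 out of these pairs, so Lin28a and Mettl14 were higher relative to all genes. Among other-lineage markers, fibroblast markers lay outside the band with 3 measured genes (median -0.136, percentile 2.25), but inside it by their mean (10.3), by ranks (5.825) and matched on the compared conditions (4.23). The immediate early list lay inside the band by its median (percentile 8.03) and outside by ranks (0.95). Gata6, of primitive endoderm, had -0.047 and 0.415, and Lef1, of the primed list, -0.254 and 0.222. Both WT emetine rates lie below the 1st percentile of that condition, which is 0, and the reads behind them are unknown. By size, Polr2k, a subunit shared by RNA polymerases, was among the lowest (0.842 and 0.153), and Cyp1b1, a cytochrome P450, among the highest (0.070 and 0.627).

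As deposited, 86.6% of genes were lower in METTL3-KO emetine, against 48.7% after centring and 15.2% against the ribosomal protein zero, so the direction over all genes depended on the zero. Ribosomal protein mRNAs themselves stood high in WT emetine, so their zero is not neutral here. The TOP list moved just inside the band, to percentile 2.67, with random lists matched on the WT mock rate.

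The third comparison asked which mRNAs decay at another rate in WT cells when translation is blocked. Histone mRNAs had a median difference of -1.17 per hour (-1.23 to -1.06), with 27 of 28 genes lower. Their median rate was 1.61 per hour in WT mock and 0.580 in WT emetine. Immediate early mRNAs (median -0.357, 31 of 33 lower) and zinc finger mRNAs (-0.270, 349 of 375 lower) were lower as well. Ribosomal protein mRNAs were higher, with a median of 0.160 (53 of 55 higher) that is near 0 (0.0059) when they serve as zero. Oxidative phosphorylation (0.142, 70 of 70 higher) and TOP translation factors (0.123, 16 of 16 higher) were higher relative to all genes but lower against the ribosomal protein zero (-0.013 and -0.031).

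H2ac8 had 1.97 per hour in WT mock and 0.506 in WT emetine, while H2bc21, the exception, had 0.495 and 0.687. The phosphatase Dusp1, which shuts off MAP kinases, had 1.17 and 0.373, and the AP-1 subunit Fosl2 0.686 and 0.439. Zfp990 had 0.570 and 0.410, and Zfp784 0.400 and 0.946. Rps20 had 0.219 and 0.489, Rpl10a 0.257 and 0.608, and the muscle paralog Rpl3l 0.323 and 0.299. Ndufa11 of complex I had 0.181 and 0.566 and Atp5l of ATP synthase 0.996 and 1.15. The elongation factor subunit Eef1b2 had 0.199 and 0.504, and the splicing regulator Hnrnpa1 0.248 and 0.422.

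The m6A machinery was lower relative to all genes (-0.089, 15 of 18 lower, percentile 1.97) and against the ribosomal protein zero (-0.243), but higher as deposited (0.021). Cbll1 had 0.684 and 0.388, the reader Ythdf1 0.429 and 0.442, and the demethylase Fto 0.243 and 0.429. Relative to all genes Ythdf1 was lower, since its rise was smaller than the common shift of 0.110. Trophectoderm markers (-0.269, 6 of 7 lower, percentile 0.30) and primed state markers (-0.264, 5 of 6 lower, percentile 0.88) were lower. Examples were Gata3 (0.800 in mock and 0.237 in emetine), Zic2 (0.780 and 0.561) and Lef1 (0.146 and -0.254). The WT emetine rate of Lef1 lies below the 1st percentile of that condition. The keratin Krt8, an exception, had 0.175 and 0.438. Chac1 had 1.15 and 0.226, the lowest of the NMD-sensitive list, whose median (-0.045) lay inside the band, and the pluripotency factor Sox2 had 0.937 and 0.485.

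As deposited, 26.6% of genes were lower in WT emetine, against 52.9% after centring and 90.3% against the ribosomal protein zero. Histone mRNAs remained near the top of the ranking of WT emetine (median change of percentile rank -8.50, percentile 36.0), and the immediate early, TOP and m6A machinery lists lay inside the band (percentiles 5.67, 93.5 and 16.3) with random lists matched on the WT mock rate. Ranks also placed the immediate early, trophectoderm and primed lists inside the band (8.58, 37.5 and 19.2), and its mean the m6A machinery list (3.24).

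The fourth comparison asked the same of cells without METTL3. Histone mRNAs had much lower rates with emetine, with a median difference of -1.34 per hour (-1.46 to -1.18) and 28 of 28 genes lower, from a median rate of 1.57 in mock to 0.234 in emetine. Unlike in WT, they also fell in the ranking (median change of percentile rank -86.9, below all random lists). Immediate early mRNAs (-0.224, 29 of 33 lower) and zinc finger mRNAs (-0.070, 282 of 375 lower) were lower too. The mRNAs described as m6A-marked were lower with a median of -0.113 (-0.155 to -0.032), and 10 of 11 were lower, at percentile 1.91. Ribosomal protein mRNAs, with a median of 0.023 (43 of 55 higher) at percentile 87.5, lay inside the band.

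H2ac7 had 1.75 per hour in mock and 0.190 in emetine, H2bc3 1.63 and 0.274, and H2bc21 0.454 and 0.429. Ier3, a stress-induced survival factor, had 1.07 and 0.332, and Id3, an inhibitor of helix-loop-helix factors, 0.602 and 0.381. Egr1 was an exception with 0.0020 and 0.357. Zfp296 had 0.968 and 0.352, Zfp239 0.371 and 0.305, and Zkscan16 -0.090 and 0.264. The mock rate of Zkscan16 lies below the 1st percentile of its condition, which is 0, and that of Egr1 just above it. Of the m6A-marked mRNAs, Sox2 had 0.585 and 0.322, Klf2 0.376 and 0.266, and Med1, the exception, 0.352 and 0.382. The stress regulator Atf4 had 0.717 and 0.273 and Tob1 0.699 and 0.371. NMD-sensitive mRNAs, with a median of -0.061 and 13 of 16 lower, lay just inside the band at percentile 2.61. Mettl3 had 0.436 and 0.272. By size, Xlr4b (0.714 and 0.141) and Pou4f2 (0.719 and 0.152) were among the lowest, and Aph1b, a subunit of gamma-secretase (0.219 and 0.684), among the highest.

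The share of lower genes was 48.1% as deposited, 49.9% after centring and 64.1% against the ribosomal protein zero. The m6A-marked list was at percentile 3.87 with random lists matched on the WT mock rate, 3.46 by ranks and 15.3 by its mean, and the zinc finger list at 3.13 by its mean, each inside the band.

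The interaction asked whether the knockout difference in mock exceeds that in emetine. It was positive, relative to all genes, for mRNAs of ribosomal proteins (median 0.141, 52 of 55 positive), histones (0.136, 24 of 28), oxidative phosphorylation (0.111, 66 of 70) and TOP translation factors (0.110, 15 of 16). It was negative for zinc finger mRNAs (-0.194, 313 of 375 negative), the m6A machinery (-0.090, 15 of 18) and primed state markers (-0.216, 5 of 6). Against the ribosomal protein zero, the medians of ribosomal protein and histone mRNAs were near 0 (0.010 and 0.0051), those of oxidative phosphorylation and TOP were negative (-0.020 and -0.021), and the m6A machinery was positive as deposited (0.017).

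For Rpl10a the interaction was 0.378 per hour as deposited and for Rpl21 0.248, while Rpl39l had -0.049. H2ac7 had 0.606, H3c2 0.241 and H2ac8 -0.039. Zscan26, at the median of the zinc finger list, had -0.086 and Zfp784 0.660. Atp5k had 0.402, the initiation factor subunit Eif3k 0.288, Cbll1 -0.222, Mettl3 0.214 and Lef1 -0.254. The value of Lef1 rests on a WT emetine rate below the 1st percentile of that condition. Klf2 had -0.254, Chac1 -0.700, Pelo -0.321 and Sox17 -1.16, and Utf1 had 0.479.

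Across the 13320 genes, the knockout difference in mock was unrelated in rank to that in emetine (Spearman's rho -0.022, Pearson's r 0.014). The emetine differences in WT and METTL3-KO were weakly related (rho 0.249, r 0.321; r was 0.193 with log2 ratios and 0.390 without recurring rates). These were the 2 correlations of differences computed, beside 6 between the rates of conditions, and genes are not independent replicates. All of these interactions include WT emetine, which stood apart, and 25.8% of genes had a negative interaction as deposited, 52.4% after centring and 85.7% against the ribosomal protein zero. With random lists matched on the WT mock rate, the TOP and m6A machinery lists lay inside the band (percentiles 91.7 and 8.27), as did the m6A machinery and primed lists by their means (5.56 and 5.07) and the primed list by ranks (14.5).

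**Figure D3:**
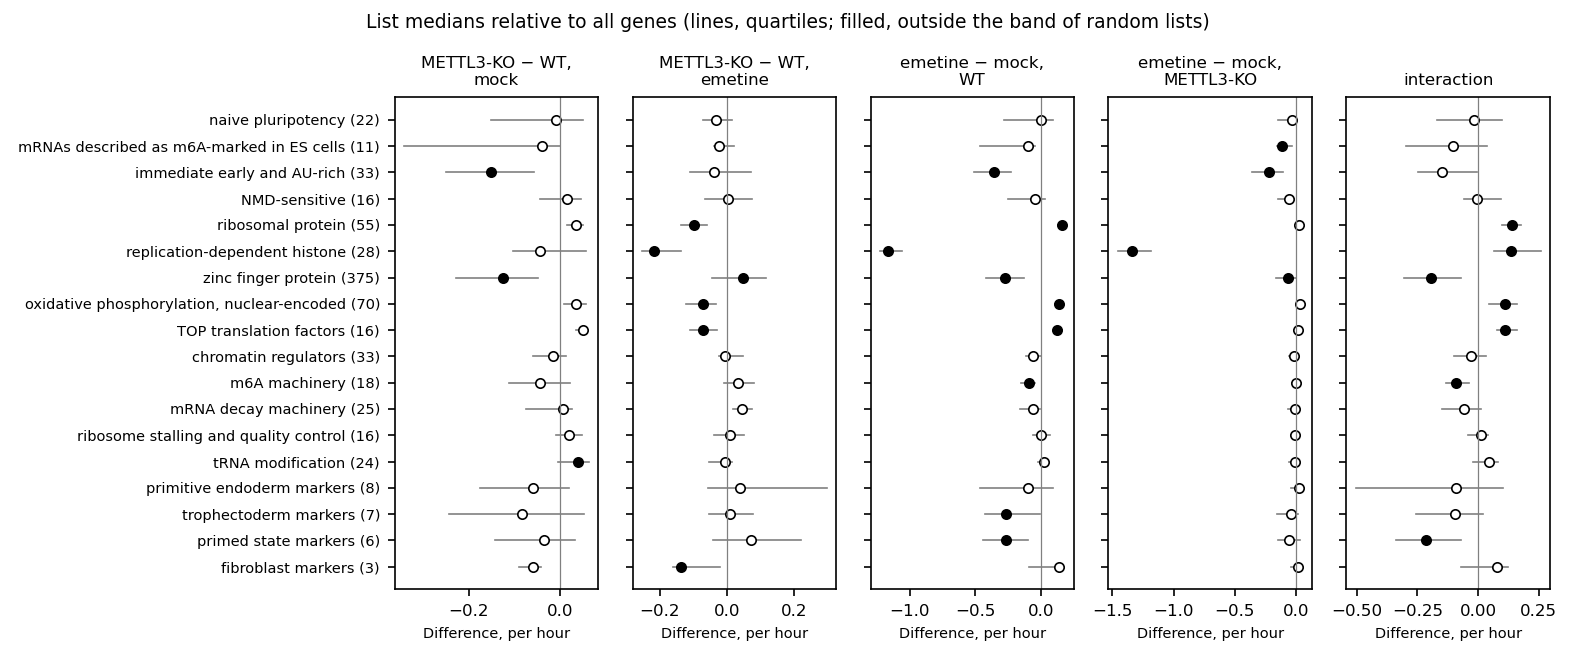
Median difference in decay rate of 18 gene lists relative to all genes (natural log per hour, horizontal axis; lines, quartiles of the members; numbers in brackets, measured genes) in the 5 comparisons, with filled points outside the band of random lists. Histone mRNAs lie at -1.17 and -1.34 with emetine, and zinc finger mRNAs at -0.124 with knockout in mock and 0.048 in emetine, where the value as deposited is -0.081; oxidative phosphorylation and TOP mRNAs change sign in both emetine panels that use WT emetine and in the interaction when ribosomal protein mRNAs serve as zero.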

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

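The tests of explanations in this part were chosen after the results were seen. The list medians and the percentiles 43.1, 4.96 and 2.12 come from the planned list analysis. Zinc finger mRNAs had a lower rate in METTL3-KO than in WT in mock, with a median difference of -0.124 per hour relative to all genes, and a higher one in emetine, with 0.0475. They stand out because the direction differs between treatments. That difference was not tested against repeated experiments, as each condition has 1 rate. A total of 463 genes had a rate in both METTL3-KO conditions and in neither WT condition, against 60 genes with rates in both WT conditions only. They are listed because no comparison uses them. Of the 463, 90 had a recurring rate in METTL3-KO mock and 93 in METTL3-KO emetine.

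The first pattern is that WT emetine orders mRNAs unlike the other conditions. Symmetric scatter from few reads is argued against for 2 slow lists, which it would leave at or below the median of all genes: in WT emetine 52 of 55 ribosomal protein genes (94.5%, Wilson interval 85.1 to 98.1) and 50 of 70 oxidative phosphorylation genes (71.4%, 59.9 to 80.7) were above it, against 3 and 1 in WT mock. For the low rank correlation, and for fast lists that moved towards the median, such scatter may still contribute: without genes with recurring rates rho was 0.188, near the 0.181 of all genes, and reads behind the remaining genes are unknown. A response to emetine that METTL3-KO cells lack and a fault in the WT emetine libraries cannot be told apart, with 1 rate per condition. The same ribosomal protein mRNAs had a median change of percentile rank of 7.39 in METTL3-KO, inside the band. But WT mock correlated less with WT emetine (rho 0.181) than with METTL3-KO emetine (0.388).

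The second pattern is the lower rate of zinc finger and immediate early mRNAs in METTL3-KO mock. A single scale factor on all rates is argued against, since zinc finger mRNAs kept 55.7% of their rate above the ribosomal protein median (95% bootstrap over genes 50.3 to 59.6) and immediate early mRNAs 65.8% (54.0 to 81.9), where histone mRNAs kept 96.9% (88.7 to 103.6). A change shared by all mRNAs of like decay rate stays open as the whole cause for both groups. Random lists matched on the mean rate of both mock conditions had 59.8% of the zinc finger difference. Of these lists, 95% lay from -0.0932 to -0.0574, above the bootstrap interval of the zinc finger median (-0.139 to -0.109). That gap may not hold once errors in the matching rate are allowed for. With a reliability of 0.764, from the correlation of both mock conditions, the median of the random lists becomes -0.0971, above the bootstrap interval. Their lower end becomes -0.122, within that interval. The reliability counts real knockout changes as error, so this correction may be too large. A first version of the test used this correction and left the explanation open. For immediate early mRNAs the percentile was 7.995, but 2.12 when matched over 4 conditions. Loss of m6A is a candidate explanation that the design names and these values leave open. The m6A-marked list was at percentile 43.1 by its median and 4.96 by its mean, both inside the band. Its members went both ways, and no map of m6A was used. A difference between the libraries other than genotype was not tested.

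The third pattern is the opposite sign of the zinc finger list in mock and emetine. A departure of the WT emetine condition alone may account for the sign in emetine. The list lost ground between WT mock and WT emetine (median change of percentile rank -25.4), but also between the METTL3-KO conditions (-7.03). The contrast cannot be made without WT emetine. A knockout effect that reverses when translation is blocked therefore remains untested.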

How the results depend on the processing

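Ranks, the removal of recurring rates, matching on the compared conditions and the ribosomal protein zero for lists were chosen after seeing the data. The share of genes with a lower rate depended on the zero, by construction, since an offset moves every gene alike. Centring gave 46.0% (knockout, mock), 48.7% (knockout, emetine), 52.9% (emetine, WT), 49.9% (emetine, METTL3-KO) and 52.4% (interaction), and the ribosomal protein zero 62.7%, 15.2%, 90.3%, 64.1% and 85.7%. The values 15.2%, 90.3% and 85.7% belong to comparisons with WT emetine, where ribosomal protein mRNAs themselves stood high. Other settings kept the side of 50%. For knockout in emetine, positive rates gave 87.5%, the 1st to 99th percentile 88.3% and no recurring rates 87.8%. The log2 ratio also gave 87.5%, by construction, since it uses the same genes and keeps the order of 2 positive rates. For emetine in WT the 1st to 99th percentile gave 25.2%, and for the interaction the log2 ratio gave 24.9%, the 1st to 99th percentile 24.4%, no recurring rates 24.8% and half-lives 25.02%. Ratios and half-lives also take the zero of each condition as a true one, which is not known. The cause of the other shifts was not tested. The rho between knockout differences was -0.0456 with log2 ratios, and that between emetine differences 0.275 with log2 ratios and 0.272 without recurring rates, while its r fell from 0.321 to 0.193 and rose to 0.390; the cause was not tested.

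Of the 90 combinations of list and comparison, 29 lay outside the band, against 24 when matched on the WT mock rate, 25 with means, 22 with ranks, 32 when matched on the compared conditions and 31 without recurring rates. Calls lost are given with each comparison in the report, and 16 were gained. Means put primitive endoderm outside with knockout in mock (percentile 0.93) and emetine (99.03), emetine in WT (0.53) and the interaction (0.07). Matching on the WT mock rate did so for NMD-sensitive (97.97), histone (100) and oxidative phosphorylation mRNAs (0.11) with knockout in mock, and fibroblast markers with emetine in WT (99.07). Matching on the compared conditions did so for histone mRNAs with knockout in mock (97.51), mRNA decay machinery with knockout in emetine (97.69) and chromatin regulators with emetine in WT (2.06). The histone percentiles of 100 and 97.51 are limited by bins too wide for that list. With emetine in METTL3-KO it did so for NMD-sensitive (2.08) and oxidative phosphorylation mRNAs (99.13). Ranks did so for immediate early mRNAs with knockout in emetine (0.95). Leaving out recurring rates did so for the m6A machinery with knockout in mock (2.23) and trophectoderm markers with emetine in METTL3-KO (0.83). Among lists outside the band, medians changed sign as follows. Centring gave 0.0475 for zinc finger mRNAs with knockout in emetine, and -0.0893 and -0.0902 for the m6A machinery with emetine in WT and in the interaction. The ribosomal protein zero gave 0.149 for the zinc finger list, 0.0043 for ribosomal protein, 0.0293 for oxidative phosphorylation and 0.0303 for TOP mRNAs with knockout in emetine. With emetine in WT and in the interaction it gave -0.0125 and -0.0204 for oxidative phosphorylation, -0.0310 and -0.0214 for TOP, and -0.243 and -0.221 for the m6A machinery. The mean of the tRNA modification list with knockout in mock was -0.00432; the cause was not tested.

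Over all 426 combinations of gene and comparison that the naming rule allows, the sign of the difference changed for 60 with centring and for 117 with the ribosomal protein zero. Among the 283 with a difference beyond the spread of genes these were 6 and 61. Of those named in the text, the ribosomal protein zero gave, with emetine in WT, -0.116 for Atp5l, -0.0777 for Fto, -0.0730 for H2bc21, -0.0901 for Hnrnpa1 and -0.00145 for Krt8. With knockout in emetine it gave 0.0535 for Mettl3, 0.00529 for Myc, 0.0293 for Ndufb11, 0.00431 for Rps3 and 0.119 for H1f4 (0.0171 with centring), and in the interaction -0.0239 for Mettl3. Each follows from the offset. Not run were the transcript features and their alternatives, the filter on low expression, the replicate block and leaving out replicates, since the table has 1 rate per condition, no expression and no exon annotation was used. Depth is unknown, so what it limits could not be measured.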

Other observations

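The screen of gene groups that share the letters of their symbol was made after the data were seen, and 232 groups gave 26, 24, 37, 25 and 33 outside the band in the 5 comparisons, against 11.6 by chance in each. Klhl genes, many of them substrate adaptors of CUL3 ubiquitin ligases, had lower rates in METTL3-KO mock (median -0.102 per hour relative to all genes, 19 of 25 lower), from a median of 0.437 in WT to 0.293. Integrin alpha genes (Itga) were higher in the same comparison, with a median of 0.099 and 2 of 10 lower. With emetine in WT cells, mRNAs of Klf transcription factors were lower (-0.381, 14 of 15), from a median rate of 0.729 to 0.438; 5 of the 15 are in the fixed lists. Those of annexins (Anxa) were higher (0.157, 0 of 10 lower). mRNAs of the large subunit of the mitochondrial ribosome (Mrpl), a group outside the fixed lists, were higher with emetine in WT (0.080, 6 of 47 lower) and lower with knockout in emetine (-0.078, 39 of 47 lower), both in comparisons that use WT emetine. Against the ribosomal protein zero both Mrpl medians change sign, and the annexin median is near 0.

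Of the 2-cell-like markers, 7 were in the table, and 4 of them (Zscan4c, Zscan4f, Zfp352 and Tcstv1) had rates in both METTL3-KO conditions and in neither WT condition. The same pattern was found in 3.03% of all genes, which gives 0.212 of 7. That share counts the 13320 genes with all rates, so it is a low baseline for genes that lack some. The WT conditions lacked a rate for more genes (1102 in mock and 1577 in emetine) than the METTL3-KO conditions (588 and 595). Zscan4c had 0.249 per hour in METTL3-KO mock and 0.343 in METTL3-KO emetine, and Tcstv1 0.444 and 0.394. Zscan4 genes are near-identical copies, so reads assigned to each are uncertain, as they are for histone, zinc finger and ribosomal protein genes with close paralogs. Housekeeping mRNAs that stood apart from their lists were Atp5l (0.996, 0.881, 1.15 and 0.871 per hour in WT mock, METTL3-KO mock, WT emetine and METTL3-KO emetine) and Rps10 (0.886, 0.924, 1.11 and 0.821). These genes were picked after their values were seen.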
